A study of Mus musculus with 6 samples.

How the data were processed

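Total RNA from the testes of mice lacking the serine protease gene Prss37 and of wild-type mice, 3 animals per genotype and 6 to 8 weeks old per the labels, had been hybridised to 6 single-colour Agilent-014868 mouse arrays after amplification and Cy3 labelling. The series' design text gives n as mice, so each array was taken as a separate animal. The p-values of single genes measure the spread between these animals. The description field of the knockout samples names Prss55 where title and source name Prss37. Samples were grouped by title.

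Spot intensity values were deposited as 1 scanner output per array, made with Agilent Feature Extraction 10.7.3.1 per the file headers (10.7 per the submitters' processing notes). The processed signal in these files is an intensity from which Feature Extraction had already removed background, per the file headers. A table of log2 values was also deposited by the submitters. Each of its columns had a median of 7.72, correlated with the log2 processed signal of its array at r above 0.999 across probes, and matched the other columns in its sorted values to within 0.001, as quantile-normalized log2 processed signals would. Its scale and centring are thus known from the values and no step is stated in the sources used here. Other per-spot columns of the deposited files, such as flags and positions, were used as they stood per the file headers.

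Each array held 43379 spots other than controls, for 41174 probes. Between 69.2% and 71.4% of these spots were well above background, 0 were saturated, and the 75th percentile of the processed signal lay between 1550 and 1707. Control spots and spots with an outlier flag (86 to 159 per array) were left out. The number of arrays limits the precision. The log2 processed signal minus the array's 75th percentile was averaged over spots of a probe. A probe was tested when it was well above background on every unflagged array of at least 1 group, with at least 2 values per group, which left 28306 probes. The brightest probe stood for a gene, which gave 18976 genes, a term that here includes transcripts without a gene symbol. Probes were named through unversioned accessions in a GRCm38.p6 RefSeq gene table (27668 probes), through a current symbol (5589) or a synonym (471), and 7446 kept the name in the file. Probe coordinates are those of the scanner files, on mm9.

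Knockout was compared with wild type in limma 3.58.1 (lmFit and eBayes, R 4.3.3) with Benjamini-Hochberg adjustment over all genes tested, and genes at adjusted p under 0.05 were called. An adjusted p for a gene comes from this fit unless a block, a left-out array or another setting is named with it. Where a probe was not well above background on any array of a group, the fold is a bound: the brighter group's mean against the mean, per array of the dim group, of the higher of the probe's own signal and the lowest signal among probes well above background. Gene lists (34, fixed with the groups, tests, alternatives and the rule for named genes before the data were examined) were tested with cameraPR at a preset correlation of 0.01, adjusted over the 34 lists. It compares the genes of a list with all other genes, so its p-values do not measure the spread between mice. The rule named Prss37, Prss55 and the tested Prss37 neighbours, the 14 largest rises and 14 largest falls by fitted log2 difference among called genes with a gene symbol, and for each list up to 4 called members or, failing any, the 2 of smallest p.

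The calls were also set against probe positions in bins of 5 Mb with at least 10 tested genes, by a one-sided hypergeometric test with Benjamini-Hochberg adjustment. This scan was chosen after the calls had been seen. Its p-values, and those of the Fisher's exact tests, take genes or probes as units and do not measure the spread between mice. Slide and scan split the arrays alike: slide 1 held replicates 1 and 2 of each genotype and slide 2 held replicate 3 of each, so values within slides and with the slide as a block are given. Alternatives were normexp with an offset of 50, quantile normalization, median centring, the deposited log2 table, other filters, flagged spots kept, other probe rules, variance trend with robust fitting, array weights, the replicate number or slide as a block, each array left out, other thresholds, and an estimated correlation or fry for lists.

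The steps were tested on simulated data for the same comparison, with 200 of 18976 genes changed and the sperm flagellum list raised by 0.2. The fit recovered 18% of genes changed by 0.3 on the log2 scale, 60% at 0.5, 78% at 0.7 and 84% at 1. Of its 122 calls, 2 were unchanged genes. Noise was drawn independently for each probe and array, without slide effects, noisier arrays or correlation between genes. These rates may therefore not hold for the real arrays.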

Results

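Transcript levels were measured in whole testes of 3 Prss37 knockout and 3 wild-type mice on C57BL/6, to find genes whose levels differ when Prss37, a testis serine protease gene of the trypsin family, is missing. Arrays of one genotype had median absolute differences between 0.05 and 0.11 on the log2 scale. The first principal component, with 39.7% of the variance, separated the genotypes. The second, with 23.0%, separated the slides. On it wild-type replicate 3 lay at -20.5 and knockout replicate 3 at -8.4, against -0.13 to 12.1 for the arrays of slide 1.

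The targeted gene was measured by a single probe on chromosome 6 from 40464853 to 40464912 (mm9), which starts at position 959 of its transcript. The Prss37 signal was 70144 ± 668 (SD, n = 3) in knockout and 117720 ± 12808 (SD, n = 3) in wild-type testes. The log2 difference was -0.71 (SE 0.07), a 1.63-fold lower level, with a limma adjusted p of 0.024. Within slides the Prss37 difference was -0.66 on slide 1 and -0.80 on slide 2, and with the slide as a block its adjusted p was 0.045. The Prss37 probe was well above background on 3 of 3 knockout arrays. The labels do not say which part of Prss37 was deleted, so whether this probe lies in the deleted part, and hence whether it checks the genotype labels, is unknown. Leaving out knockout replicate 1, 2 or 3 or wild-type replicate 1 took the adjusted p of Prss37 to 0.070, 0.12, 0.13 and 0.093. Prss55, a related testis protease gene on chromosome 14 from 64694275 to 64694333 that 1 label field names for the knockout samples, had a log2 difference of -0.16 (SE 0.09, adjusted p = 0.36), with signals of 52597 ± 878 (SD, n = 3) in knockout and 60478 ± 9455 (SD, n = 3) in wild type. Its difference was -0.08 on slide 1 and -0.31 on slide 2, with an adjusted p of 0.29 with the slide as a block, and -0.07 without wild-type replicate 3 and -0.24 without wild-type replicate 2.

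**Figure D1:**
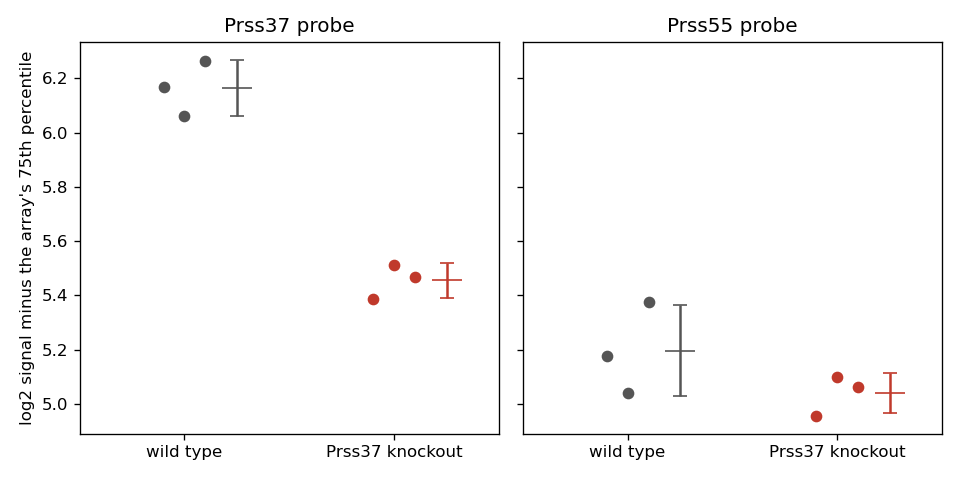
Log2 processed signal relative to the array's 75th percentile (y axis) of the Prss37 and Prss55 probes in 3 wild-type and 3 knockout testes. Points are arrays and the bar beside them is the mean with its SD. The Prss37 points of the genotypes do not overlap, with means of 5.46 in knockout and 6.16 in wild type, while those of Prss55 do.

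None of the 8 tested neighbours of Prss37 passed the test. The sugar-digesting enzyme gene Mgam had a log2 difference of 0.39 (adjusted p = 0.12), Prss58 -0.25 (0.17), the trypsinogen gene Prss2 0.42 (0.24) and Try5 0.17 (0.15). Agk, Dennd11, Ssbp1 and Clec5a had differences of -0.02, -0.05, 0.11 and -0.22. Mgam passed with the mean of a gene's probes (adjusted p = 0.047). With an array left out none of the 8 passed, and the differences ran from 0.21 to 0.57 in Prss2, from -0.48 to -0.001 in Clec5a and from 0.07 to 0.13 in Ssbp1.

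Genes that fell in knockout testes included Ltk, a receptor tyrosine kinase, at least 4.54-fold lower, the chemokine receptor gene Ccr7, 2.12-fold lower, and the phospholipase gene Pla2g4e, at least 1.81-fold lower. Genes that rose included Zfp85os (1.99-fold), the zinc finger gene Zbtb21 (at least 1.98-fold), the transporter gene Atp13a5 (at least 1.82-fold) and the complement receptor gene C3ar1 (at least 1.63-fold). In all, 230 genes were higher and 237 lower, and most differences were small. The median size among the 467 called genes was 0.41 on the log2 scale, and 340 were under 0.5. With bounds used for genes not well above background on any array of a group, 0 rises and 4 falls reached 2-fold. A gene symbol was available for 358 of the 467. All 467 had no overlap between genotypes, where 31.6% of all tested genes did not overlap and chance gives 10%. Their same direction on both slides follows from that. Both rest on the arrays that gave the calls, so neither is separate support for them. With the slide as a block 30 genes were higher and 49 lower, and 73 of the 467 kept their call. The counts also moved by over 1.5 times when an array was left out, to 9 higher and 37 lower without knockout replicate 1, 0 and 2 without replicate 2, 0 and 4 without replicate 3, 1 and 5 without wild-type replicate 1, and 463 and 358 without wild-type replicate 2. Without any filter on dim probes, 2 genes were higher and 6 lower. With normexp, whose offset of 50 draws dim signals together, 256 of the 467 kept their call. The log2 differences there were -1.17 for Ltk, -0.72 for Pla2g4e, 0.48 for Zfp85os, 0.42 for Zbtb21, 0.60 for Atp13a5 and 0.19 for C3ar1, against fitted differences of -3.55, -3.03, 0.99, 1.21, 1.95 and 0.98, and C3ar1 lost its call (adjusted p = 0.25).

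Ccr7 had a log2 difference of -1.08 (SE 0.12, adjusted p = 0.031). Among the other falls, Spg11, which is mutated in a hereditary spastic paraplegia, was 2.09-fold lower (-1.06, SE 0.05, adjusted p = 0.0023), with 1 of its 2 other probes lower at unadjusted p under 0.05. Mxd3 was 1.99-fold lower, Serinc4 1.94-fold, Nfam1 1.91-fold and Rbm31y 1.86-fold. Adgrf4, Depdc7, Eps8l1, Olfr1362, Lzts1 and Psd4 were not well above background on any knockout array and were at least 1.56-fold, 1.27-fold, 1.38-fold, 1.93-fold, 1.21-fold and 1.92-fold lower. Among the other rises, Serpina3a was 1.77-fold higher, Yipf7 1.75-fold, Olfr27 1.72-fold, the vitamin E carrier gene Afm 1.68-fold, the cytokine gene Il9 1.67-fold and Fsip1 1.62-fold. The bile salt exporter gene Abcb11 was 1.61-fold higher, and Pilra, Pcdhb12 and Ugt3a1 were 1.60-fold, 1.60-fold and 1.59-fold higher, Ugt3a1 being well above background on 1 of 3 wild-type arrays. Afm and Nfam1 each had 1 other probe, which did not move in that direction at unadjusted p under 0.05. Of 133 called genes with another tested probe, 84 had one that did. With the mean of a gene's probes the log2 differences of Afm and Nfam1 shrank from 0.75 to 0.44 and from -0.93 to -0.41, with their calls lost (adjusted p of 0.50 and 0.10), and that of Spg11 to -0.68. With normexp the differences shrank from -0.99 to -0.55 in Mxd3, from -0.96 to -0.51 in Serinc4, to -0.42 in Nfam1, from 0.79 to 0.51 in Olfr27, from 0.68 to 0.43 in Pilra and to 0.41 in Pcdhb12, and were -0.70 in Adgrf4 and -0.41 in Olfr1362, with the calls kept. Calls were lost there in Ugt3a1 (from 0.67 to 0.23, adjusted p = 0.065), Depdc7 (-0.26, 0.11), Eps8l1 (-0.30, 0.099), Lzts1 (-0.26, 0.22) and Psd4 (-0.36, 0.053). With the slide as a block, 22 of the 44 called named genes, Prss37 and list members included, lost their call.

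Called genes lay close together on chromosome 2. Between 115 and 125 Mb (mm9), 29 of 118 tested genes were called (24.6%), 14 higher and 15 lower, against 432 of 18437 elsewhere (2.34%). The 2 bins of this run were the bins past the scan's threshold, with adjusted p of 3.1e-10 and 3.8e-07. The run held Ltk, Pla2g4e, Spg11 and Serinc4 among the named falls and Fsip1 among the named rises, and 8 of the 20 genes with the smallest p. Within 10 Mb of the Prss37 probe 3 of 164 genes were called, and within 10 Mb of the Prss55 probe 6 of 228. Chromosome 2 as a whole, the run included, had 79 of 1449 genes called (5.45%), and its part outside the run 50 of 1331 (3.76%). The X chromosome had 33 of 675 (4.89%) and chromosome 4 10 of 1131 (0.884%). The adjusted Fisher's exact p of the whole chromosomes 2, X and 4 was 5.6e-10, 0.0016 and 0.0011.

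**Figure D2:**
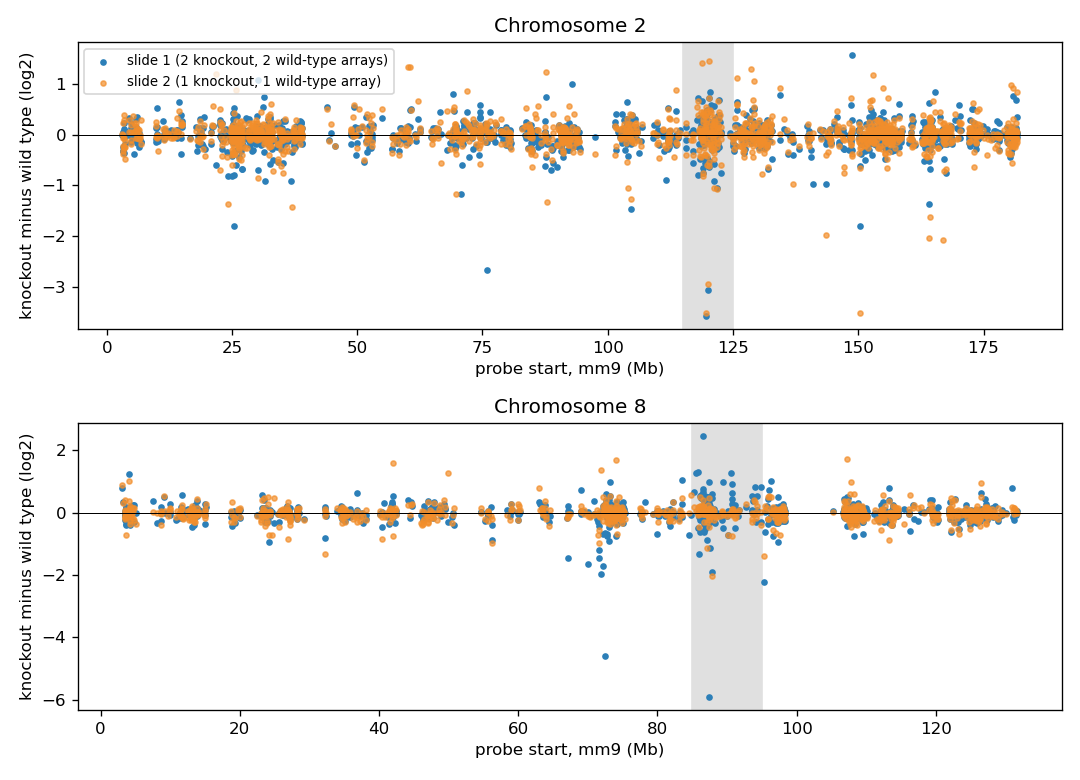
Log2 difference between knockout and wild type (y axis) by probe start on mm9 in Mb (x axis) for tested genes of chromosomes 2 and 8, with slide 1 (2 arrays per genotype) in blue and slide 2 (1 array per genotype) in orange. Shading marks 115 to 125 Mb on chromosome 2, where 29 of 118 genes were called, and 85 to 95 Mb on chromosome 8, where the slides differ: Klf1 lies at -5.91 on slide 1 and -0.46 on slide 2.

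Macrophage and antigen presentation markers were higher as a list (adjusted p = 0.0080), with 18 of 21 members above 0 and a median log2 difference of 0.23. The list missed the threshold with an adjusted p of 0.055 with an estimated correlation. None of these members passed the test singly or when adjusted over the list alone. The scavenger receptor gene Cd163 had 0.36 (adjusted p = 0.072) and the apolipoprotein gene Apoe 0.29 (0.093). The list median was 0.23 on slide 1 and 0.20 on slide 2, with an adjusted p of 0.0013 with the slide as a block.

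Acrosome and zona binding genes were higher as a list (adjusted p = 0.0080, median 0.08, 23 of 27 above 0), a call lost at adjusted p = 0.35 with an estimated correlation, 0.053 with normexp and 0.054 with the deposited table, and the median was 0.05 with quantile normalization and with the mean of a gene's probes. Zan, the sperm zonadhesin gene, rose 1.30-fold (adjusted p = 0.042, 0.056 with normexp) and its other probe did not move in that direction at unadjusted p under 0.05. Sperm-egg fusion genes were also higher as a list (adjusted p = 0.013, median 0.09, 11 of 12 above 0), with 0 called over all genes and 3 higher when adjusted over the list alone. This call was lost at adjusted p = 0.35 with an estimated correlation, 0.053 with normexp and 0.081 without wild-type replicate 2, and the median was 0.15 without wild-type replicate 3. Tmem95, needed for sperm to fuse with the egg, had 0.39 (adjusted p = 0.060) and 4930451I11Rik 0.27 (0.062). With the slide as a block the adjusted p of the acrosome and fusion lists was 0.0081 and 0.016, and their medians were 0.11 and 0.14 on slide 1 and 0.05 and 0.01 on slide 2. Ribosomal protein genes had a median of 0.04 (adjusted p = 0.013, 69 of 83 above 0), which was -0.002 after quantile normalization (adjusted p = 0.79). This call was also lost at adjusted p = 0.79 with an estimated correlation, 0.29 with normexp and 0.75 with the deposited table, and with a median of 0.03 (0.13) without knockout replicate 2 and 0.02 (0.41) without wild-type replicate 2. Rpl10a and Rpsa had 0.15 and 0.12. The ribosomal list's medians were 0.05 on slide 1 and 0.01 on slide 2, with an adjusted p of 0.016 with the slide as a block.

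Immediate early and heat shock genes were lower as a list (adjusted p = 0.039, median -0.14, 17 of 21 below 0), with 0 called over all genes and 2 lower when adjusted over the list alone. This call was lost at adjusted p = 0.33 with an estimated correlation, 0.065 with normexp (median -0.08), 0.064 with quantile normalization, 0.065 with the deposited table and 0.12 with the mean of a gene's probes. It was also lost without knockout replicate 2 (0.085) or 3 (0.061) and without wild-type replicate 1 (0.15, median -0.09). The phosphatase gene Dusp1 had -0.37 (adjusted p = 0.051) and Btg2 -0.34 (0.062). The list median was -0.14 on slide 1 and -0.02 on slide 2, with an adjusted p of 0.039 with the slide as a block. With an estimated correlation 0 of the 34 lists passed, where 9 had an unadjusted p under 0.05 at the preset correlation, and with fry 1 passed (macrophage markers, adjusted p = 0.042). Another split of the 6 arrays into 3 and 3 gave 8 lists.

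**Figure D3:**
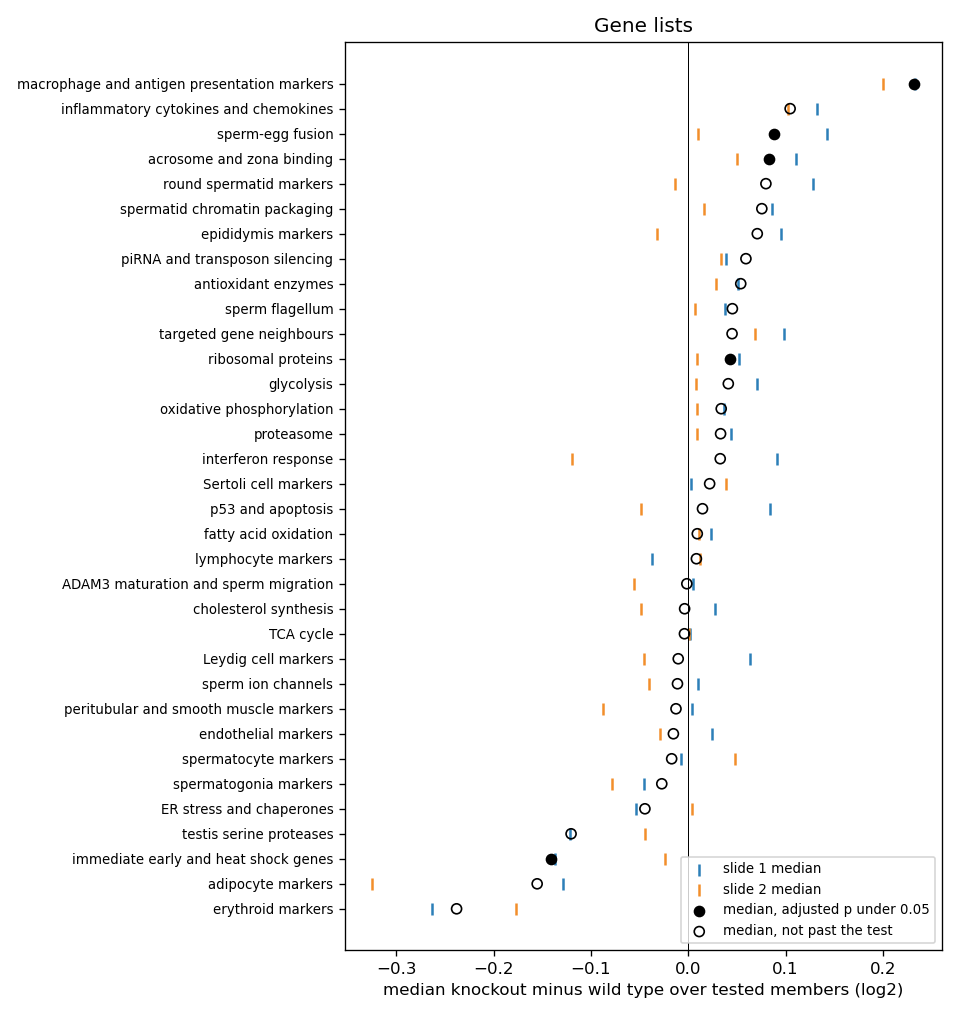
Median log2 difference between knockout and wild type (x axis) over the tested members of each of 34 gene lists (y axis). Circles are medians over all arrays, filled where the list passed at the preset correlation, and ticks are medians within each slide. The macrophage list lies highest, at 0.23 overall and 0.20 on slide 2.

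The remaining lists did not pass. Among germ cell lists, round spermatid markers had an adjusted p of 0.069 (median 0.08), spermatid chromatin packaging 0.16, piRNA and transposon silencing 0.25, spermatogonia 0.28, sperm flagellum 0.37, ADAM3 maturation and sperm migration 0.70, sperm ion channels 0.95 and spermatocytes 0.98. Without knockout replicate 1 or wild-type replicate 3 the round spermatid list passed (adjusted p of 0.047 and 0.0040, medians 0.08 and 0.13), while its median was 0.05 without wild-type replicate 1 (0.15) or 2 (0.41). The chromatin packaging list also passed without these arrays (0.0099 and 0.015, medians 0.12 and 0.10), and its median of 0.08 was 0.03 without knockout replicate 2 (0.57). The round spermatid median was 0.04 with quantile normalization (0.35) and with the deposited table (0.31). Over the alternatives other than single left-out arrays, the chromatin packaging median ran from 0.007 to 0.10. Of the members of the germ cell lists, Dnmt3l, a cofactor of DNA methyltransferases, rose 1.43-fold. The meiotic cohesin gene Rec8 rose 1.27-fold and the sperm calcium channel gene Catspere1 fell 1.28-fold (adjusted p = 0.081 with normexp). Traf3ip2, a signalling adaptor that entered the round spermatid list through the synonym Act1 and is not a marker of these cells, fell 1.31-fold, and its log2 difference of -0.39 was -0.11 with normexp (adjusted p = 0.38). Of 20 tested testis serine proteases (adjusted p = 0.21), Prss46 rose 1.33-fold and Prss52 fell 1.30-fold. In the meiotic entry gene Stra8 the difference was -0.42 (adjusted p = 0.058), and in Calr3 and Adam6b of the ADAM3 list it was -0.23 (0.094) and -0.24 (0.075).

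Among other cell types, adipocyte markers had an adjusted p of 0.059 (median -0.16) and Cidea fell 1.34-fold. The adipocyte list passed without knockout replicate 2 (0.039) or wild-type replicate 2 (0.047). Epididymis markers had 0.44, peritubular 0.55, Leydig 0.66, Sertoli 0.70, lymphocyte 0.87, endothelial 0.95 and erythroid markers 0.95. Ptgds, a prostaglandin D synthase gene in the Leydig list, rose 1.40-fold, the B cell gene Ms4a1 rose 1.51-fold (log2 difference 0.59, and 0.34 with normexp) with its other probe not moving in that direction at unadjusted p under 0.05, the T cell gene Cd8b1 fell 1.33-fold and the heme synthesis gene Alas2 rose 1.44-fold. Median, mean and test differed in sign for the Leydig list (-0.01, 0.09, up), erythroid (-0.24, -0.09, up; median -0.06 without knockout replicate 2, 0.11 without wild-type replicate 1 and -0.53 without wild-type replicate 2), Sertoli (0.02, -0.03, up), endothelial (-0.02, 0.01, up), spermatocyte (-0.02, 0.001, up), interferon (0.03, -0.03, down) and sperm ion channel lists (-0.01, 0.001, down).

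Of the metabolic and stress lists, oxidative phosphorylation had an adjusted p of 0.075, proteasome 0.18, antioxidant enzymes 0.21, inflammatory cytokines and chemokines 0.21, glycolysis 0.44, fatty acid oxidation 0.55, ER stress 0.55, p53 and apoptosis 0.61, TCA cycle 0.91, interferon response 0.91 and cholesterol synthesis 0.95, and the Prss37 neighbours had 0.55. Without wild-type replicate 1 the oxidative phosphorylation list passed (0.017, median 0.03), and its median was 0.02 without knockout replicate 2 (0.31) or wild-type replicate 2 (0.49). This median was -0.004 with quantile normalization (0.91) and -0.003 with the deposited table (0.85). The electron carrier gene Etfb rose 1.28-fold and catalase (Cat) rose by 0.26 on the log2 scale, and Gpx2, a glutathione peroxidase gene, fell 1.26-fold, and with normexp these 3 calls were lost (adjusted p of 0.056, 0.095 and 0.074). Insig1, a brake on sterol synthesis, had -0.61 (adjusted p = 0.057) and Cyp51 -0.36 (0.068). Over the 34 lists, 15 of 811 distinct tested members were called, against 467 of all 18976 genes tested, so list members were not called at a higher share.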

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

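The 4 arrays of slide 1 alone and the genes outside the chromosome 2 run were alternatives chosen after seeing the data. The counts of 230 higher and 237 lower genes became 2 and 6 with no filter on dim probes, 125 and 150 with the mean of a gene's probes, 691 and 579 with a variance trend and robust fitting, 644 and 529 with array weights, 30 and 49 with the slide as a block, and 5 and 16 on slide 1 alone, where there are fewer arrays. With each probe on its own 132 were higher. Thresholds gave 959 and 907 at adjusted p under 0.1, 2 and 11 with a fitted fold of at least 2, and 20 and 37 at unadjusted p under 0.05 with that fitted fold. With bounds in place of fitted folds against groups in which no array was well above background, these were 0 and 4, and 9 and 26. Leaving out an array gave 0 to 463 higher and 2 to 358 lower genes, highest without wild-type replicate 2. The cause was not tested for these shifts. Slide 1 alone and the left-out arrays leave fewer samples, but that does not account for the rise without wild-type replicate 2. The fitted array weights ran from 0.43 in wild-type replicate 3 to 2.10 in knockout replicate 3, with 0.63 in wild-type replicate 2. Outside the run on chromosome 2, 198 were higher and 213 lower.

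Replicate numbers were not taken to pair the mice, since the labels do not say that they pair animals. Same-numbered arrays deviated together at r = -0.03, -0.03 and 0.16 across genes, which does not settle whether they do. The pair at 0.16 shared slide 2, and differently numbered pairs on slide 1 had 0.14 and 0.11. With the replicate block 0 genes were higher and 2 lower (Ltk and Pla2g4e), and Prss37 had -0.71 with an adjusted p of 0.13. Prss37 stayed lower throughout. It missed the threshold at -0.71 (adjusted p = 0.093) with no filter on dim probes and at -0.66 (0.11) on slide 1 alone, and lay between -0.76 and -0.66 with an array left out (adjusted p from 0.029 to 0.13). Prss55 missed the threshold in all 20 alternatives.

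The 5 lists past the test became 1 with normexp, 3 with quantile normalization, 2 with the deposited table, 8 on slide 1 alone, 0 with an estimated correlation and 1 with fry, and the cause was not tested. Leaving out an array gave 4 to 7. The macrophage list missed its threshold only with the estimated correlation among the alternatives run. Of single lists against alternatives, 742 outcomes were the same, 25 lost and 15 gained a call (in the round spermatid, chromatin packaging, adipocyte and oxidative phosphorylation lists). Of named genes, 1435 were the same, 350 lost and 62 gained a call. None of these reversed, where a result called in neither setting counts as the same. Between 69.2% and 71.4% of spots were well above background. Folds of genes not well above it on any array of a group are bounds.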

Other observations

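Most tests of the 3 patterns weighed here were chosen after the result was seen. The only exceptions were the comparison of wild-type replicates 1 and 2 on chromosome 2 and the counts over other splits of the arrays. The slide block was an alternative fixed in advance, but its use on a slide difference in the macrophage list came after related values were seen. On chromosome 8 between 85 and 95 Mb (mm9), wild-type replicate 3 differed from the other wild-type testes in several genes and lay at or towards the knockout levels in some of them. Klf1, an erythroid transcription factor gene, had log2 levels of 1.24 and 1.32 in wild-type replicates 1 and 2, -4.27 in replicate 3, and -4.76, -4.50 and -4.73 in the knockouts. Misp3 had 0.17 and 0.32 against 2.68, with 2.64, 2.74 and 2.68 in the knockouts. Scoc had 1.41 and 1.32 against 0.51, between those and the knockout levels of 0.04, 0.05 and 0.03. Mylk3 had -4.24 and -3.83 against -4.85, between those and the knockout levels of -6.50, -5.39 and -6.88. These genes were named after their values were seen, and none of the 4 was called.

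For chromosome 8, the bins at 85 and 90 Mb ranked first and second by the mean distance of wild-type replicate 3 from the other wild-type arrays (0.43 and 0.35, median of all bins 0.15). A slide difference is argued against for the top bin, which ranked 381 by the same distance of knockout replicate 3, and stays open for the second, which ranked 23 (0.16, median of all bins 0.09). A knockout sample in place of wild-type replicate 3 is argued against, since over the 427 genes called without it its median position from the knockouts (0) to the other wild types (1) was 0.62 (quartiles 0.28 and 0.89), against 0.09 to 0.12 for each knockout and 0.58 and 1.16 for each other wild type left out the same way over as many genes of smallest p. Over the 50 genes of smallest p it was 0.16, with 22 of these on chromosome 8. The 2 top bins were neighbours, at a distance of 1 bin. Apart from them, the chromosome 8 bins at 70 and 65 Mb ranked 3 and 8 (0.30 and 0.25). The chromosome 2 bin at 85 Mb ranked 5 (0.29), and ranked 1 for knockout replicate 3 (0.43). A segment of another strain segregating among the mice may produce neighbouring top bins. That stays a hypothesis, with genotypes not analysed here and C57BL/6 as the labelled background.

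For the calls on chromosome 2, 0 of 10000 shuffles of the calls reached the 16 calls of the fullest bin (highest 14), which argues against calls placed at random. The shuffles used the same calls and bins as the scan that picked the run, so they are not separate support for it. Both treat neighbouring genes as independent. A lost segment is argued against by falls making up 51.7% of the calls (exact 95% interval 32.5% to 70.6%). Sequence differences under single probes as the whole cause are argued against by 47.1% of other probes moving (8 of 17), against 15.6% for genes not called elsewhere (one-sided Fisher's exact p = 0.0023, and 0.016 with 1 other probe per gene, 5 of 10). For genes called elsewhere it was 55.8% (two-sided Fisher's exact p = 0.61 against the run). These counts do not address sequence differences under more than 1 probe of a gene. Genes varying between mice stay open. The run's best rank was 206 for wild-type replicate 1 against 2 and 305 for knockout replicate 1 against 2. Each of these compares 2 mice only, and the chromosome 8 bin that set wild-type replicate 3 apart ranked 271 and 327 by them. The 1.83% of genes called within 10 Mb of Prss37 (2.63% for Prss55) say nothing about a segment carried along with the gene, since the run was chosen for its calls and lies on another chromosome than either. The slide test did not bear on this run: it took the bin with the largest mean change on slide 1, which was the chromosome 8 bin. That bin ranked 268 on slide 2. The run's own bins ranked 2 and 10 on slide 1 and 7 and 30 on slide 2. Each slide held equal numbers of both genotypes, so a shift shared by a slide's arrays cancels in the comparison. Such a shift cannot by itself give these calls. A segment of another strain in 1 of the lines may account for a run with rises and falls but stays open, since the rank of 30 missed the limit of 22 set for it, and an effect of Prss37 loss on this region was not tested.

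For the macrophage markers, the adjusted p of 0.0013 with the slide as a block cannot decide on a slide difference. Each slide held equal numbers of both genotypes, so a shift shared by the arrays of a slide cancels in the comparison. The list median was 0.23 on slide 1 and 0.20 on slide 2, above 0 on each. A lower share of germ cells would raise other somatic markers alike. The mean was 0.21 over 21 macrophage genes and 0.01 over 66 Sertoli, Leydig, peritubular and endothelial genes (one-sided permutation p = 0.0043 over genes, which are not independent). The macrophage list was chosen for its rise, and genes rather than mice were permuted, so this p-value does not decide the question. More macrophage RNA may be the source but is undecided. Of the 6 markers brightest in wild type, with Apoe left out because other cells make it too, 5 lay above 0. Lyz2 had 0.31, Cd74 0.36 and Fcgr3 -0.004, and H2-Ab1 and Cd74 were below 0 on slide 2 (-0.13 and -0.18).

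The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 230 higher and 237 lower genes and was the only 1 of the 10 to reach either, the highest other count in a direction being 1. It gave 5 lists past the test, and 4 of the splits, the real included, gave as many, the highest other giving 8.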
